A study of Mus musculus with 6 samples.

How the data were processed

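The series holds 6 RNA-seq libraries from vertebral growth plates of mice at postnatal day 7, 3 labelled WT and 3 labelled CKO. Per the labels' protocols, total RNA was extracted from growth plates with TRIzol, and libraries were made with a stranded Illumina TruSeq mRNA kit. A further label calls the cells primary chondrocytes, and the genotype label of the CKO samples speaks of a knockdown. The labels give no sex, litter, dissection day or sequencing batch, and do not say that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

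Per the submitters' processing notes, the authors worked with the mm10 build and with Trimmomatic, HISAT2, Bowtie2 and DESeq2. Versions, roles and order, the read counter, its strand setting and the annotation are not given in the sources used here. The authors deposited a table of raw counts per gene symbol and a table of FPKM. The deposited counts are whole numbers with totals of 21917987, 20543646 and 22432860 in WT replicates 1 to 3 and 21006340, 21650101 and 22108112 in CKO replicates 1 to 3. The deposited FPKM values equal the counts divided by the column total and by a gene length that is the same in all 6 libraries, so they are no independent measurement and served only as an alternative. A list of 22173 symbols was deposited, 5386 of them with no count in any library, and 21070 symbols matched GENCODE M21 (GRCm38), from which printed coordinates were taken. The share of genes on autosomes and the window around Mapk7 used RefSeq positions on the same build. Because the strand setting of the counting is not given, reads of genes that overlap on opposite strands may be mixed. Of the 111 genes called with the replicate block, 51 overlap an annotated gene on the other strand. The share over all tested genes was not computed, so this count does not show that the called genes overlap more often than others.

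Library scaling used TMM factors, genes were kept by edgeR's filterByExpr, and 12922 genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, default settings, R 4.3.3) on the deposited counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit without a block was fixed as the main design before the data were examined, with the replicate number as a block listed as an alternative. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries. At these totals 3 counts, taken as the limit that a count of 0 allows, lie below the lowest level reported as called, and such limits cover counting error only.

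The replicate numbers come from the sample titles. Deviations of libraries from their group means correlated across genes at 0.723 for WT and CKO replicate 1, 0.526 for replicate 2 and 0.644 for replicate 3. All 3 lie above the threshold of 0.1 fixed for taking the numbers as pairs, so blocked values are given wherever they change a call. WT replicate 2 also correlated with CKO replicate 3 (0.615) and WT replicate 3 with CKO replicate 2 (0.537), so the pairing rests mainly on replicate 1 against replicates 2 and 3. No pair of libraries agreed within counting noise. The closest, CKO replicates 2 and 3, gave a chi-square of 5.96 per degree of freedom over genes with at least 20 counts. WT replicates 2 and 3 gave 10.7, and the next lowest value was 64.8, for WT and CKO replicate 1. Replicates 2 and 3 of a group were thus far closer to each other than any other libraries. Calls from replicates 2 and 3 alone rest on this small spread, which may be smaller than that between separate animals.

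Gene lists of pathways, chondrocyte zones and other cell types, 35 in number, were fixed before the data were examined. The 31 with at least 3 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. List medians are of log2 CPM differences and are the same with and without the block. With an estimated correlation 0 lists passed in either fit. Genes were named by a rule fixed beforehand, namely Mapk7, then among called genes with a mean log2 CPM of at least 1 and non-overlapping groups the 12 largest changes in each direction (the 10 smallest p where none were called), and up to 4 members of each list by smallest p. As the fit without a block called none, the rule was applied again to the blocked fit after the data were seen, and genes named outside it were chosen after their values were seen. In the report these are Col11a2, Matn3, Col2a1, Sox9, Scx, Mfap4 and Pecam1, and the closing section names others, among them Ngp, Ihh and Bglap.

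The scripts were tested on simulated data, with 8 draws of counts for the 12922 genes of the CKO against WT comparison, in each of which 200 genes were changed. With gene-wise dispersions the blocked fit recovered 21.3% of genes changed 1.5-fold, 68.8% of those changed 2-fold and 96.8% of those changed 4-fold, and 9.88% of its calls were false, above the nominal rate. With dispersions on the smooth trend 4.07% were false. Without the block, 0.187% of the 2-fold and 40.3% of the 4-fold changes were recovered with gene-wise dispersions, with 0 false calls. A simulated list of 20 genes shifted by 0.5 on the log2 scale was called with the preset correlation and not with an estimated one (camera adjusted p = 0.922), while 0 of 31 random lists were called by either. Genes were drawn independently of each other in the simulation. It therefore cannot show how often the preset correlation gives false calls for lists whose genes vary together.

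Alternatives were other scaling factors (RLE, library totals), no filter or a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), leaving out each library, and the replicate block. Added after the data were seen were combinations of the block with these, edgeR's newer quasi-likelihood method, fits to 2 of the 3 pairs, a batch term for replicate 1 and a fit to replicates 2 and 3 alone. Differences between replicate 1 and replicates 2 and 3, and their interaction with genotype, were tested in the same way and also chosen after the data were seen. In the interaction all residual spread comes from replicates 2 and 3, since replicate 1 has 1 library per genotype. Leaving out a library in the fit without a block also leaves replicate 1 unequal between the genotypes, so a change there can reflect the difference between replicate sets.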

Results

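RNA sequencing was carried out on vertebral growth plates of mice at postnatal day 7, the cartilage zone that lengthens the vertebrae after birth. The samples were 3 wild-type (WT) libraries and 3 libraries from Col2a1cre;Mapk7f/f mice (CKO), in which Cre recombinase driven by the cartilage collagen promoter Col2a1 removes floxed Mapk7 from chondrocytes. Mapk7 encodes the kinase ERK5. The labels name the tissue as growth plate and the cells as primary chondrocytes for all 6 samples. It is not clear from them whether the RNA came from tissue or from isolated or cultured cells, and this was not tested. Of 15 genes of red blood cells, 0 had enough counts to be tested. Total counts per library ran from 20543646 in WT replicate 2 to 22432860 in WT replicate 3, and 12922 of the 22173 genes in the table had enough counts to be tested. The comparison asks how loss of Mapk7 alters gene expression in growth plate chondrocytes.

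Mapk7 was lower in the CKO libraries, and the difference did not pass the test. Its level was 30.5 ± 3.53 CPM (counts scaled to the library's effective size; mean ± SD, n = 3) in WT and 23.4 ± 2.15 CPM in CKO. The values were 32.6, 32.5 and 26.4 CPM in WT replicates 1 to 3 and 25.8, 22.8 and 21.6 CPM in CKO replicates 1 to 3. The log2 fold change was -0.38 ± 0.16 (SE), with an edgeR quasi-likelihood adjusted p of 1.0 and an unadjusted p of 0.0484. With the replicate number as a block it was -0.38 ± 0.13, adjusted p = 0.318, and the CKO library was the lower one in all 3 pairs. Mapk7 lies on chromosome 11 from 61488812 to 61494406 on the minus strand (GRCm38, the mm10 build), and its count covers all exons, so it does not measure the floxed part alone. The end of Mapk7 overlaps Mfap4 on the other strand by 89 bases. Mfap4 was at 2.79 ± 0.663 CPM in WT and 5.32 ± 4.66 CPM in CKO.

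With the replicate block, 9 of 24 cartilage matrix genes fell and 2 of 15 fibroblast genes rose in the CKO libraries, and neither list passed the camera threshold with an estimated correlation (adjusted p = 0.316 for each). Acan, the core protein of the main cartilage proteoglycan, fell by 1.23 ± 0.11 (SE) on the log2 scale, and the type XI collagen gene Col11a1 fell by 1.19 ± 0.13. Fgfr3, a receptor that restrains growth of the growth plate, fell by 1.92 ± 0.18. Tnn, which encodes the matrix glycoprotein tenascin-N, rose by 3.47 ± 0.42, and the fibrillar collagen gene Col3a1 rose by 0.96 ± 0.12. The rise of Tnn was 2.07 in pair 1, 3.96 in pair 2 and 4.26 in pair 3. In total, 49 genes were higher and 62 lower at an adjusted p under 0.05, of which 29 and 47 changed at least 2-fold. All 111 genes differed in the same direction in all 3 pairs of libraries, which selection by the blocked fit favours, so it is no independent support. These calls belong to the blocked fit. Without the block, the design fixed before the data were examined, edgeR called 0 genes higher and 0 lower, with a smallest adjusted p of 0.260. At an unadjusted p under 0.05, 213 genes were then higher and 267 lower. DESeq2 without the block called 28 and 42, and limma-voom called 0 and 0. The libraries of replicate 1 stood apart from the other 4 along the first principal component, which held 68.3% of the variance, and genotype separated along the second, which held 15%. With the block and scaling by library totals alone, 3 genes were higher and 4 lower. With only pairs 1 and 3, 3 genes were higher and 8 lower, and with only pairs 2 and 3, 876 and 1056.

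**Figure D1:**
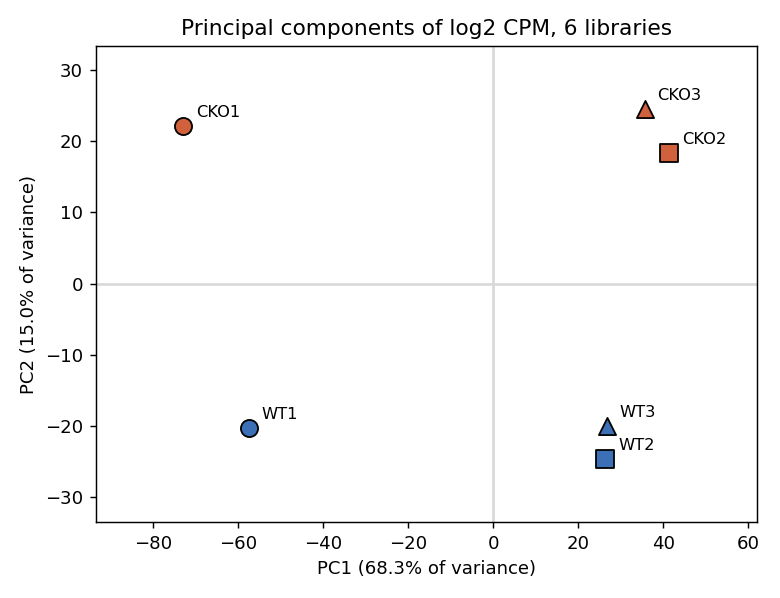
Principal component scores of log2 CPM for the 6 libraries, with PC1 on the horizontal and PC2 on the vertical axis, blue for WT and orange for CKO, and circles, squares and triangles for replicates 1, 2 and 3. Both replicate 1 libraries lie on the negative side of PC1 (68.3% of variance), and WT and CKO lie on opposite sides of PC2 (15%).

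Among the fixed lists, that of resting and proliferating chondrocyte matrix genes held the most genes that fell with the block. Of its 24 genes, 9 fell and 15 did not pass the test with the block, while 22 were lower and 1 higher when adjusted over the list alone. Besides Acan and Col11a1, these were Col11a2 (-1.68 ± 0.23), Col27a1 (-1.38 ± 0.10), Hapln1 (-1.23 ± 0.12), Comp (-1.02 ± 0.13), Matn3 (-1.15 ± 0.16), Epyc (-1.04 ± 0.11) and Cytl1 (-1.82 ± 0.21), as log2 fold changes with SE. Hapln1 encodes the link protein that holds aggrecan on hyaluronan. Col27a1, on chromosome 4 from 63214004 to 63334991, was at 291 ± 83.7 CPM (mean ± SD, n = 3) in WT and 112 ± 32.2 CPM in CKO, and Comp was at 4220.3 ± 283 CPM and 2078 ± 189.7 CPM. Col2a1, the main cartilage collagen, had a log2 fold change of -0.97 ± 0.21 (adjusted p = 0.106), and Sox9, the master transcription factor of cartilage, one of -0.61 ± 0.10 (adjusted p = 0.0619). The list's median log2 difference was -1.17 (camera adjusted p = 1.0e-18 with the block and 7.7e-14 without it, adjusted p = 0.316 with an estimated correlation), and 23 of 24 genes were lower. Its pair medians were -0.75, -1.29 and -1.39, so the fall was smallest in pair 1. In the same libraries the fibroblast and macrophage lists had medians of 0.51 and 0.39, and the adipocyte list one of -0.999.

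The list of prehypertrophic and hypertrophic chondrocyte genes also fell, with a median log2 difference of -0.32 (camera adjusted p = 0.00686 with the block, adjusted p = 0.47 with an estimated correlation). In the fit without a block it was not called without WT replicate 1 (-0.0934, adjusted p = 0.3), CKO replicate 2 (-0.13, 0.307) or CKO replicate 3 (-0.0852, 0.198). Fgfr3 was its only member past the test among 20 tested, at 254 ± 139 CPM in WT and 78 ± 68.8 CPM in CKO, and 6 were lower and 1 higher when adjusted over the list alone. Mef2c, a transcription factor of hypertrophy that is also an ERK5 substrate, had a log2 fold change of -0.98 ± 0.18 (adjusted p = 0.0712), and the hypertrophic channel gene Panx3 one of -1.30 ± 0.24 (adjusted p = 0.0771). In the osteoblast list 1 of 16 tested genes fell, Omd, which encodes the matrix protein osteomodulin (-1.66 ± 0.16), and the bone collagen gene Col1a1 was at 0.77 ± 0.13 (adjusted p = 0.0619).

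Further genes with the largest falls were Klk10, a secreted serine protease (-2.33 ± 0.25), Slc16a14 (-2.33 ± 0.36), Nrk (-1.74 ± 0.23), Chdh, a choline dehydrogenase (-1.58 ± 0.23), Fry (-1.57 ± 0.11), Susd5 (-1.57 ± 0.18), Scube1 (-1.44 ± 0.20), Wscd2 (-1.44 ± 0.18) and the laminin gene Lamb3 (-1.38 ± 0.18). Klk10 went from 16.3 ± 3.29 CPM in WT to 3.22 ± 0.577 CPM in CKO. Among genes that rose, Gfra2, a receptor for glial cell line-derived neurotrophic factors, increased most after Tnn (2.53 ± 0.20), from 2.31 ± 0.439 to 13.4 ± 2.69 CPM. Il1rl1, the receptor of interleukin 33, rose by 2.39 ± 0.29, from 64.1 ± 21.1 to 399 ± 251 CPM. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, rose by 1.51 ± 0.19, and Cnn1, a calponin of contractile cells, by 2.06 ± 0.17. Tnfaip6, a hyaluronan-binding protein, rose by 1.59 ± 0.19, Prima1 by 1.54 ± 0.21, Medag by 1.41 ± 0.22, and the myeloid genes Clec4n and Ccl6 by 2.21 ± 0.25 and 1.76 ± 0.20. The macrophage list had a median of 0.39 in the same libraries, with pair medians of 0.39, 0.82 and -0.02. Clec4n and Ccl6 were higher in replicates 2 and 3 than in replicate 1 (by 1.33 and 1.09 log2 units), while the macrophage list was lower there (median -0.98).

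**Figure D2:**
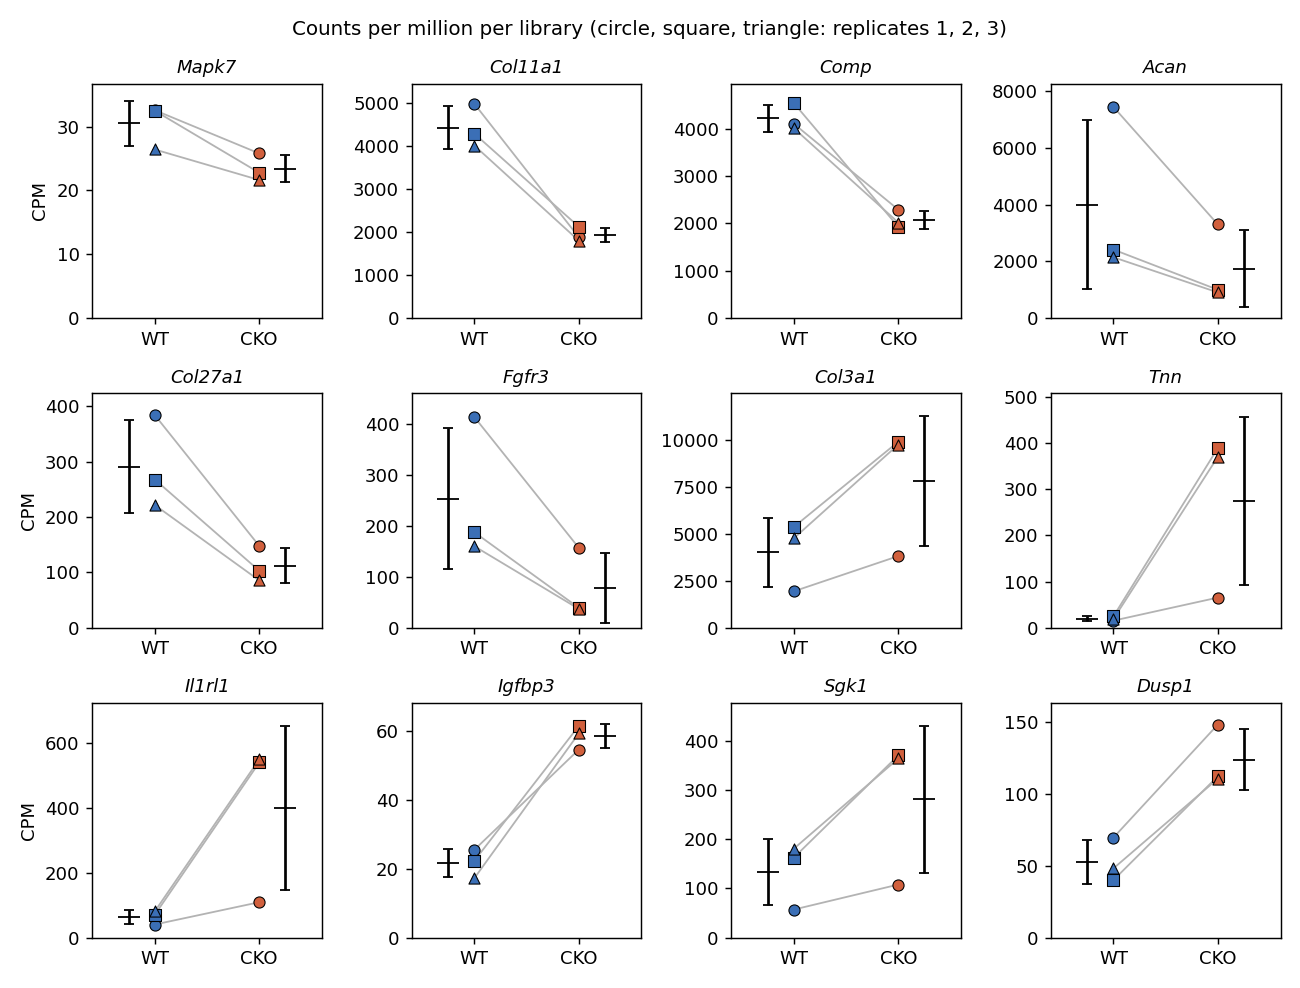
CPM on linear axes that start at 0 for 12 genes in WT (blue) and CKO (orange) libraries, with circles, squares and triangles for replicates 1, 2 and 3, grey lines joining libraries of the same replicate number, and black bars for the mean ± SD of 3 libraries. Acan differed more between replicates than between genotypes, yet CKO lay below WT in each pair, while Col11a1 was at 4437 ± 501 CPM in WT and 1938 ± 169 CPM in CKO.

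Genes of tendon, perichondrium and annulus fibroblasts rose as a list, with a median log2 difference of 0.51 (camera adjusted p = 3.3e-05 with the block and 1.2e-04 without it, adjusted p = 0.316 with an estimated correlation). Of 15 tested genes, 2 rose with the block, Col3a1 and Dpt (2.22 ± 0.33), and 8 were higher when adjusted over the list alone. Dpt encodes dermatopontin, a collagen-binding matrix protein. Its rise was 3.23 in pair 1, 1.49 in pair 2 and 1.93 in pair 3, with 90.4, 32.5 and 37.6 CPM in CKO replicates 1 to 3. Lum had a log2 fold change of 0.64 ± 0.12 (adjusted p = 0.0808) and Postn one of 0.77 ± 0.16 (adjusted p = 0.101). The tendon transcription factor gene Scx had a log2 fold change of 0.16 ± 0.14 (adjusted p = 0.779). The protease list had a median of 0.14 (camera adjusted p = 0.0457 with the block and 0.274 without it, adjusted p = 0.47 with an estimated correlation). Of its 17 genes, 2 rose, the stromelysin gene Mmp3 (1.04 ± 0.12) and Htra1 (0.75 ± 0.11), which encodes a serine protease, while the metalloprotease gene Adamts9 was at -1.42 ± 0.26 (adjusted p = 0.076). In the fit without a block, the list's median without WT replicate 1 was -0.0021 (adjusted p = 0.959). Its pair medians were 0.35, 0.04 and 0.08. In the insulin-like growth factor list 2 of 16 genes rose, the binding protein genes Igfbp3 (1.44 ± 0.16) and Igfbp2 (1.26 ± 0.17), while the growth factor gene Igf2 was at -0.97 ± 0.16 (adjusted p = 0.0619). Among BMP and TGF-beta targets 1 of 17 genes rose, Pmepa1 (0.93 ± 0.14), a feedback inhibitor of TGF-beta signalling, and Serpine1 was at 1.73 ± 0.28 (adjusted p = 0.0575).

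The inflammatory cytokine and chemokine list passed with the block (median 0.52, camera adjusted p = 6.4e-05), and not in the fit without it (adjusted p = 0.0891) or with an estimated correlation (adjusted p = 0.47). In the fit without a block, its median without WT replicate 1 was -0.0565 (adjusted p = 0.983). Its pair medians were 0.49, 0.63 and 0.06. Of 17 tested genes, 3 rose, Il1rn, the interleukin 1 receptor antagonist (1.29 ± 0.12), and the chemokines Cxcl5 (0.97 ± 0.12) and Ccl7 (0.96 ± 0.13), and 5 were higher when adjusted over the list alone. Il6 had a log2 fold change of 2.54 ± 0.83 (adjusted p = 0.282). In the immediate early and heat shock list (median 0.21, camera adjusted p = 0.0358, adjusted p = 0.493 with an estimated correlation), 1 of 19 genes rose, the phosphatase gene Dusp1 (1.26 ± 0.12), from 52.7 ± 15.3 to 124 ± 21.3 CPM. In the fit without a block this list was not called without WT replicate 3 (median 0.18, adjusted p = 0.0707) or CKO replicate 1 (median 0.19, adjusted p = 0.619). The macrophage marker Lyz2 was at 0.74 ± 0.17 (adjusted p = 0.133). In the ERK5 pathway list, whose median was -0.33 (camera adjusted p = 0.15), 1 of 12 genes rose, the kinase gene Sgk1 (1.04 ± 0.11). The ERK5 target genes Klf2 and Klf4 were at -0.62 ± 0.14 (adjusted p = 0.125) and -0.44 ± 0.13 (adjusted p = 0.225), and Nr4a1, of the same list, was at 0.98 ± 0.25 (adjusted p = 0.157).

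All 20 genes of the S phase list had positive differences, with a median of 0.28 and pair medians of 0.30, 0.24 and 0.27 (camera adjusted p = 5.7e-06 with the block and 1.2e-04 without it, adjusted p = 0.316 with an estimated correlation), but 0 of them passed the test on their own. Ccne1, which encodes cyclin E1, had the smallest p, at 0.60 ± 0.15 (adjusted p = 0.157). The G2 and M phase list had a median of 0.26 (camera adjusted p = 9.7e-04, adjusted p = 0.47 with an estimated correlation), 14 of 20 genes were higher and 0 were called. The glycolysis and hypoxia list had a median of 0.27 (camera adjusted p = 9.5e-06 with the block, adjusted p = 0.316 with an estimated correlation) with 20 of 22 genes higher. Only Adm, the adrenomedullin gene, rose in it (0.75 ± 0.11), and the mitophagy gene Bnip3 was at 0.53 ± 0.13 (adjusted p = 0.148). Cholesterol synthesis genes had a median of -0.15 (camera adjusted p = 0.0251, adjusted p = 0.493 with an estimated correlation), with 18 of 20 genes lower and 0 called. In the fit without a block, the S phase and glycolysis lists were not called without CKO replicate 1 (0.13, adjusted p = 0.151, and 0.0973, adjusted p = 0.25). The cholesterol list was not called without WT replicate 1 (-0.0698, adjusted p = 0.222), WT replicate 3 (-0.14, 0.0706), CKO replicate 2 (-0.0739, 0.34) or CKO replicate 3 (-0.0714, 0.27). The fibroblast list had a median of 0.51 in the same libraries.

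**Figure D3:**
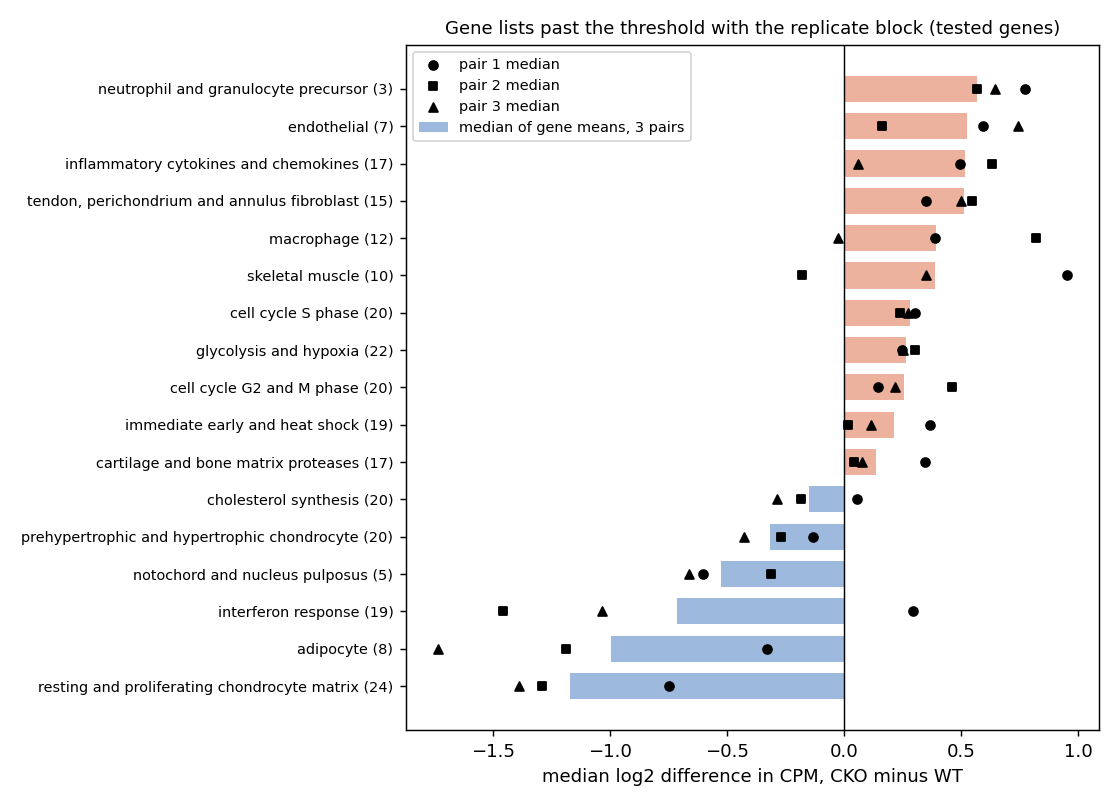
Median log2 difference in CPM, CKO minus WT, for the 17 lists past the camera threshold with the replicate block, with the number of tested genes in parentheses, bars for the median over the genes' means of the 3 pairs and circles, squares and triangles for pairs 1, 2 and 3. The chondrocyte matrix list has the lowest median (-1.17), and the pairs part most in the interferon list, from -1.46 in pair 2 to 0.30 in pair 1.

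Interferon response genes had lower median levels in CKO than in WT in replicates 2 and 3, and were near the same low level in both libraries of replicate 1. The median of the 19 tested genes was 93.3 CPM in WT replicate 2 and 101.9 CPM in WT replicate 3, against 27.3 and 31.8 CPM in CKO replicates 2 and 3. In replicate 1 it was 3.96 CPM in WT and 3.52 CPM in CKO. Isg15, a ubiquitin-like protein induced by interferon, was at 3.96, 224 and 212 CPM in WT replicates 1 to 3 and at 3.57, 56.5 and 63.6 CPM in CKO replicates 1 to 3. Over all 3 pairs the list had a median of -0.72 (camera adjusted p = 1.2e-06 with the block, 0.0374 without it, adjusted p = 0.493 with an estimated correlation), 0 genes were called and 8 were lower when adjusted over the list alone. In the fit without a block the median was 0.0232 without WT replicate 2 (adjusted p = 0.919), -0.0839 without WT replicate 3 (adjusted p = 0.649) and 0.15 without CKO replicate 1 (adjusted p = 0.983). Stat1, the transcription factor of the interferon response, was at -0.92 ± 0.30 (adjusted p = 0.29). The difference between CKO and WT was more negative in replicates 2 and 3 than in replicate 1 for 16 of the 19 genes by a test of the interaction (edgeR adjusted p under 0.05), in which the lone WT and CKO libraries of replicate 1 are assumed to vary like replicates 2 and 3.

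**Figure D4:**
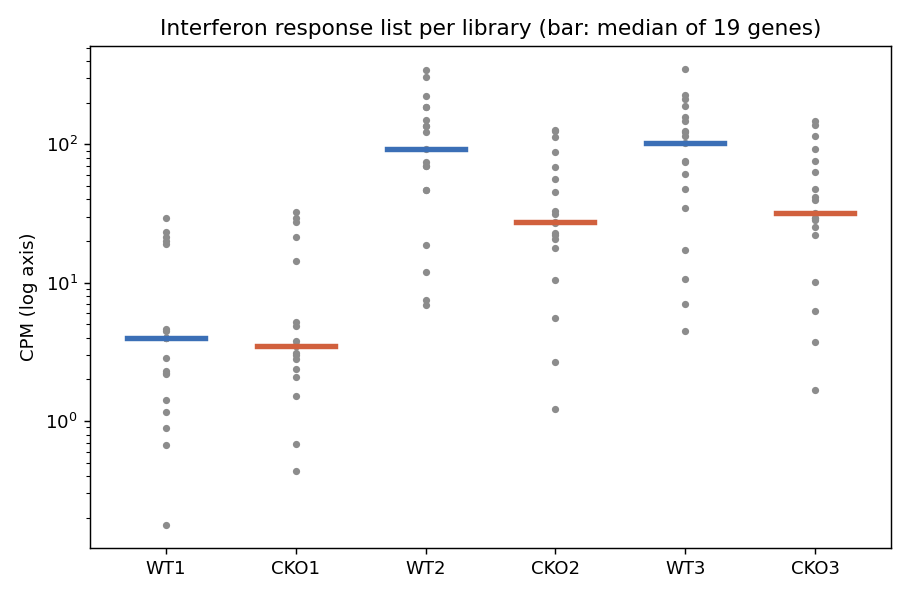
CPM, on a log axis, of the 19 tested interferon response genes (grey points) in each library, ordered by replicate number, with horizontal bars at the median, blue for WT and orange for CKO. The medians of WT replicates 2 and 3 (93.3 and 101.9 CPM) lie above those of CKO replicates 2 and 3 (27.3 and 31.8 CPM), and both replicate 1 libraries lie below 4 CPM.

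Marker lists of other cell types moved in both directions. The skeletal muscle list had a median of 0.39 (camera adjusted p = 0.0358 with the block, 0.724 without it, adjusted p = 0.493 with an estimated correlation), the endothelial list one of 0.53 (adjusted p = 0.0358, 0.5 without the block, adjusted p = 0.47 with an estimated correlation) and the macrophage list one of 0.39 (adjusted p = 0.00332, adjusted p = 0.493 with an estimated correlation). The neutrophil list, with 3 tested genes, had a median of 0.57 (adjusted p = 0.00686, 0.203 without the block, adjusted p = 0.47 with an estimated correlation). The adipocyte list had a median of -0.999 (adjusted p = 5.8e-05, adjusted p = 0.47 with an estimated correlation) and all 8 genes were lower, among them Lpl, lipoprotein lipase, at -0.79 ± 0.13 (adjusted p = 0.0576). The notochord list, with 5 tested genes, had a median of -0.53 (adjusted p = 0.0428, adjusted p = 0.47 with an estimated correlation), its keratin gene Krt19 at -1.34 ± 0.32 (adjusted p = 0.136). None of the genes in these lists was called on its own. Pair medians were 0.95, -0.18 and 0.35 for muscle, 0.59, 0.16 and 0.74 for endothelium and 0.78, 0.57 and 0.64 for neutrophils. The muscle, endothelial and neutrophil lists were lower in replicates 2 and 3 than in replicate 1 (medians of -2.36, -0.78 and -1.86). In the fit without a block several medians changed direction when a library was left out, which also leaves replicate 1 unequal between the genotypes. Without CKO replicate 1 the medians were -0.53 for muscle (adjusted p = 0.0396, a call in the opposite direction), -0.17 for endothelium (adjusted p = 0.634), -0.14 for neutrophils (adjusted p = 0.41) and 0.0867 for macrophages (adjusted p = 0.683). Without WT replicate 2 they were -1.12 for neutrophils (adjusted p = 0.229) and 0.0989 for macrophages (adjusted p = 0.458). Without WT replicate 3 they were -0.0921 for muscle (adjusted p = 0.649) and -0.79 for neutrophils (adjusted p = 0.849), and without WT replicate 1 the adipocyte and notochord lists were not called (-0.58, adjusted p = 0.0714, and -0.69, adjusted p = 0.271). Several of these markers were near 0 in replicates 2 and 3, among them Pecam1, the endothelial adhesion gene, at 102 and 251 counts in the replicate 1 libraries and at most 6 counts in the others.

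The remaining lists did not pass the threshold with the block. The medians were -0.37 for resting zone markers (camera adjusted p = 0.0748), -0.23 for osteoblasts and osteocytes (0.15), -0.02 for osteoclasts (0.778), -0.18 for hedgehog targets (0.352), -0.08 for FGF and ERK1/2 feedback targets (0.875) and -0.08 for BMP and TGF-beta targets (0.75). They were 0.01 for WNT targets (0.336), -0.27 for the insulin-like growth factor axis (0.15), -0.03 as a mean for the unfolded protein response (0.778), 0.09 for nuclear oxidative phosphorylation (0.0776) and -0.15 for apoptosis and p53 targets (0.15). Neural and Schwann cell genes had a median of 0.04 (0.75) and epidermal genes one of -0.24 (0.306 with the block and 0.04 without it). Without the block the epidermal list was not called with an estimated correlation (adjusted p = 0.386). Nor was it called without WT replicate 3 (-0.28, adjusted p = 0.0719) or CKO replicate 1 (-0.43, adjusted p = 0.109). Ptch1, a hedgehog receptor and target, was at -0.57 ± 0.15 (adjusted p = 0.183). The erythroid and B cell lists had 0 and 1 tested genes, and the mitochondrially encoded genes and Xist were not in the table used here.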

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

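The tests of library depth, sex chromosomes, other cell types, interferon levels and single libraries, and of the interaction, were chosen only after the results were seen; those of abundant genes and of other splits of the samples were written before their results were seen.

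In an edgeR test of whether the difference between CKO and WT in the replicate 1 pair matched that in the other pairs, 2494 of the 12922 genes were called, 1515 with a more positive and 979 with a more negative difference in replicates 2 and 3. Replicate 1 has 1 library per genotype, which the test assumes to vary like replicates 2 and 3, so these calls compare that pair of libraries with the others and do not show that the effect of genotype differed. Y-linked genes, which no comparison used, gave a signal in 2 libraries only. Their summed counts over Ddx3y, Kdm5d, Eif2s3y and Uty were 1090 in WT replicate 1 and 352 in CKO replicate 1, and at most 1 in each of the other 4 libraries, against 3 counts as the limit that a count of 0 allows.

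The replicate 1 libraries stood apart from the other 4, with 2839 genes higher and 2930 lower in replicates 2 and 3. Depth is argued against as the cause, since the mean total count of replicate 1 was 0.990 times that of the others. The difference was not confined to the sex chromosomes, since 96.9% of the genes called between these samples lie on autosomes. Most genes lie on autosomes, so a high share was fixed in advance, and the share over all tested genes was not computed. This share cannot decide whether the sex of the animals was a cause. Cells of other types carried in replicate 1 may account for part of it, since 77.3% of 66 muscle, neutrophil, macrophage, endothelial, adipocyte and B cell markers were higher in both replicate 1 libraries than in all 4 others, against 31.1% of the 13802 other genes with at least 10 counts in a library and 6.67% by chance, and of these 66 markers 41 had enough counts over the 6 libraries to be tested and 0 belonged to another list. The neutrophil gene Ngp had 431 and 350 counts there and at most 1 in the others, but dilution by such cells runs against the cartilage matrix list, which was higher in replicate 1 (median -1.25 for replicates 2 and 3 minus replicate 1). Y-linked counts ran along the same split. Summed counts of Y-linked genes, which only males carry, were 1090 and 352 in WT and CKO replicate 1 and at most 1 in each of the others. The replicate 1 libraries had similar totals (21917987 in WT and 21006340 in CKO), so these counts also differed between the genotypes within pair 1. A replicate block does not remove a difference within a pair. Whether the sex of the animals differed between the genotypes there was not tested. Whether sex or a difference in dissection, culture or sequencing batch caused the split stays open and untested. As the labels give no group for this split, no biological explanation was tested.

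Lower cartilage matrix genes with higher fibrous genes in CKO were weighed against technical explanations. A few abundant genes taking counts are argued against, since the median of the cartilage matrix list was -1.19 once the 10 most abundant genes were left out. A smaller share of chondrocytes in the CKO libraries could raise the markers of all other types alike, and such a rise was not seen in the tested lists. Markers too low to be tested moved both ways in pair 1. From WT to CKO the endothelial genes Pecam1 and Tie1 went from 102 to 251 and 46 to 95 counts. The neutrophil gene Ngp went from 431 to 350 and the adipocyte gene Retn from 63 to 47. In replicates 2 and 3 these markers were near 0, so they cannot show a dilution there. The adipocyte list median lay below the fibroblast list median in all 3 pairs (mean of the pair differences -1.55 ± 0.80, SD). Of the adipocyte genes 8 of 8 were lower, and of the fibroblast genes 13 of 15 were higher. This comparison was chosen after both medians were seen. It cannot decide on a smaller share of chondrocytes in which only some other types rose. Of the 11 lists of other cell types 5 had negative medians, and the smallest unadjusted camera p among these with an estimated correlation, that of the notochord list, was 0.0471 without the block and 0.145 with it. A smaller share of chondrocytes, a larger share of fibroblasts and an effect of genotype within chondrocytes all stay open as hypotheses.

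The interferon genes were lower in CKO in replicates 2 and 3, and not in the single pair of libraries of replicate 1. A lack of counts in replicate 1 is argued against, since the lower of the median counts in its libraries was 72, and over 14 genes with a mean of at least 50 counts there the pair medians were 0.22, -1.32 and -0.85. A single high WT library is argued against as well, since the lower of the WT medians in replicates 2 and 3 lay 1.55 log2 units above the higher CKO median. This covers single libraries only. WT replicates 2 and 3 were close to each other (chi-square of 10.7 per degree of freedom). The labels do not say that they came from separate animals, so a source that both shared cannot be judged. Whatever raised these genes in replicates 2 and 3 (medians of 93.3 and 101.9 CPM in WT, against 3.96 in WT replicate 1) may be part of a batch, and with 1 WT and 1 CKO library in replicate 1 its contribution and that of genotype stay open.

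Whether chance can account for the counts was limited by the number of splits. With the block, the real labels gave 111 genes and the highest of the other 3 splits within pairs gave 0, and 1 of the 4 splits gave as many. For lists, 17 passed against a highest of 7, and again 1 of 4 splits gave as many. Without the block, all 10 splits gave 0 genes, and for lists the real split gave 13 and the highest other 10, with 1 of 10 splits as large. The highest other split for lists put WT replicates 1 and 3 with CKO replicate 1. These splits are too few for a share under 0.05.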

How the results depend on the processing

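Results from combinations with the replicate block, fits to some of the replicates, the batch term and the newer quasi-likelihood method were chosen after the data were seen. The fit without a block called 0 genes in each direction with TMM, RLE or library totals, under each filter, with limma-voom, on FPKM and with the newer method. DESeq2 called 28 higher and 42 lower. Leaving out single libraries gave 0 to 6 higher and 0 to 1 lower, with 6 and 1 without CKO replicate 1 and 0 and 1 without WT replicate 1. The replicate block called 49 higher and 62 lower. With the block, the counts were 56 and 72 by the newer quasi-likelihood method, 202 and 241 by DESeq2, 65 and 89 by limma-voom, 46 and 59 with RLE factors, 3 and 4 with library totals only, 75 and 138 with no filter and 47 and 60 with the mean CPM filter. Pairs 2 and 3 gave 876 and 1056, pairs 1 and 3 gave 3 and 8, and pairs 1 and 2 gave 34 and 77. A batch term for replicate 1 gave 170 and 201, and replicates 2 and 3 only gave 777 and 990. The cause of these differences in count was not tested. All 111 genes called with the block had the same sign in each of these settings, and all 111 were called again with the batch term and in replicates 2 and 3 only. These settings use the same counts from which the genes were selected, so they are no independent support. Mapk7 had a negative fold change throughout (-0.48 to -0.33, adjusted p from 0.0278 to 1.0) and passed with the block in pairs 2 and 3 (-0.40, adjusted p = 0.0278) and in replicates 2 and 3 only (-0.40, adjusted p = 0.0460). Between 10 and 17 lists passed with the preset correlation and 0 with an estimated one, with or without the block. The block brought the protease, inflammatory, muscle, neutrophil and endothelial lists past the threshold, took the epidermis list below it and changed no other list call. List medians changed sign when single libraries were left out, ranging from -0.0021 to 0.34 for proteases, -0.0565 to 1.36 for inflammatory genes, -2.08 to 0.15 for interferon, -0.53 to 0.88 for muscle, -0.17 to 1.21 for endothelium and -1.12 to 1.16 for neutrophils, which were at -0.0332 with no filter, with or without the block. Mfap4 ranged from -0.0804 to 1.25. Leaving out a library in the fit without a block also leaves replicate 1 unequal between the genotypes. Its part in these changes of sign was not tested. No other named gene changed sign. At 20543646 to 22432860 counts per library, genes at or under 3 counts in both groups give no fold.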

Other observations

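The tests here were chosen after the data were seen, except that of the genes near Mapk7.

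The genes named next were called with the block, lie outside the lists and were chosen after their values were seen, and no test of their functions as a group was made. Papss2, which makes the sulfate donor, had a log2 fold change of -1.18 ± 0.14 (SE), the chondroitin sulfotransferase gene Chst11 one of -0.81 ± 0.11 and the xylosyltransferase gene Xylt1, which starts the sugar chains, one of -0.80 ± 0.12, each in edgeR's quasi-likelihood fit. The collagen receptor gene Itga10 (-0.84 ± 0.12), the calcium channel gene Trpv4 (-0.66 ± 0.10) and Wwp2 (-0.82 ± 0.11) also fell, as did the imprinted genes Peg3 (-1.31 ± 0.19) and Peg10 (-1.24 ± 0.16). Peg3 went from 578 ± 22.1 CPM in WT to 244 ± 84.2 CPM in CKO (mean ± SD, n = 3). Among genes that rose were the elastic fibre gene Fbn2 (1.25 ± 0.18), Col5a3 (0.95 ± 0.12), the matricellular genes Thbs2 (0.88 ± 0.11) and Ccn5 (1.13 ± 0.13), and the neurotrophin receptor gene Ntrk3 (1.62 ± 0.14).

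Between the replicate sets, the interferon list had the largest median difference of the lists tested. Its median was 3.26 log2 units higher in replicates 2 and 3, with 18 of 19 genes called higher (camera adjusted p = 2.6e-09, adjusted p = 0.544 with an estimated correlation). The inflammatory list had a median of 1.15, with 11 of 17 genes called higher and 1 lower. The skeletal muscle list had a median of -2.36 with 9 of 10 genes called lower, and the adipocyte list one of -2.08 with 6 of 8 called lower. The cartilage matrix list had a median of -1.25, with 16 genes called lower and 3 higher, and the hypertrophic list one of -1.02, with 11 lower and 5 higher. These 5 lists passed with the preset correlation and did not with an estimated one (adjusted p = 0.573 for the inflammatory and adipocyte lists, 0.434 for the muscle and hypertrophic lists and 0.529 for the cartilage list). The growth plate hedgehog ligand gene Ihh had 93 and 40 counts in WT and CKO replicate 1 and at most 3 in the other 4 libraries, and the osteoblast gene Bglap 115 and 130 against at most 4.

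Across genes, the log2 differences of pairs 2 and 3 correlated at 0.633, while those of pair 1 correlated at 0.00 with pair 2 and 0.199 with pair 3. Genes are not independent replicates. Of 1743 genes called in replicates 2 and 3 alone and tested in all 6 libraries, 1147 (65.8%) had the same sign in pair 1.

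Flanking DNA of another strain, carried along with the floxed allele, was tested as a hypothesis for differences near Mapk7. Gene positions were those of the RefSeq annotation of GRCm38, which held 12896 of the 12922 tested genes, Mapk7 included. Within 10 Mb of the gene 11 of 222 tested genes (4.95%) had an unadjusted p under 0.05 with the block, against 1484 of 12673 elsewhere (11.7%). The odds ratio was 0.393 (Fisher's exact test, two-sided p = 0.000947), with 0 genes called in the window, so this window held fewer such genes than the rest and no excess was seen.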
